A study of Homo sapiens with 6 samples.

How the data were processed

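RNA was sequenced from 6 samples of T24 cells, named in the labels as 3 vehicle and 3 LPS plus nigericin replicates. The labels describe RNA extraction and sequencing by a service company, give hg38 as the genome build per the submitters' processing notes, and name more than 1 company for extraction. The authors deposited a table of raw counts per Ensembl gene, with 1 column per library, per the file headers. The aligner, the counting tool, the annotation release, the strand setting, and whether reads or fragments were counted are not given in the sources used here. Each column was assigned to a sample by the library name in its label. The values were whole numbers, and 0 columns belonged to no sample.

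The table held 37871 genes, 6043 of them at 0 in every library, and 37840 identifiers matched a symbol, with 31 unmatched. Where identifiers shared a symbol, the one with the highest count kept it. In all, 517 identifiers shared a symbol or, like the 31 unmatched, had none. Library totals were 66180407 to 89152224 counts, so counting error was small for genes above a few CPM and the spread between replicates sets the precision. The common biological coefficient of variation was 0.268. Each pair of replicates differed by far more than sampling noise (chi-square per degree of freedom 24.1 to 207), so none was treated as the same library deposited again.

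Genes were filtered with edgeR's filterByExpr, which left 19170, and normalized with TMM factors. The comparison of treated with vehicle libraries used edgeR 4.0.16 in R 4.3.3 with a robust quasi-likelihood fit, an F test and Benjamini-Hochberg adjustment at 0.05, with the group as the only term. Standard errors are the absolute log2 fold change divided by the square root of F. CPM use TMM-scaled library sizes. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 on log2 CPM with a prior count of 2, adjusted over 27 lists, of which 831 of 896 names matched. No exact permutation of 3 against 3 libraries can give a two-sided p below 0.1. Coordinates, exons, transcript length and GC content came from GENCODE 29 on the same assembly, which held 18620 (97.1%) of the tested genes, and 13976 tested protein-coding genes had a GC value.

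The lists, the 12 inflammasome, receptor and cytokine genes, the tests and the naming rule were fixed before the data were examined. The rule named the 6 largest rises and the 6 largest falls among called genes with a mean of at least 5 CPM in the higher group and no overlap between groups, the 3 members with the smallest p in each list past camera's threshold that moved in its direction, the 1 member with the smallest p in each other list, and the 12 fixed genes. Members that make up a count of 5 or fewer in a list, LY96 and CD14 of the TLR4 list, and the ribosomal and nuclear RNAs in the closing section, were named after their values were seen. XIST and genes on Y were not named, and some genes that the rule or a small count would name are not reported here.

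Alternatives were edgeR's RLE factors, library totals without composition factors, DESeq2 1.42.0, limma-voom, no count filter, a stricter filter of 1 CPM in 3 libraries, the replicate number as a block, a test against a 2-fold change (glmTreat), camera with an estimated correlation, fry, and leaving out each library in turn. A fit without mitochondrial and 5.8S rRNA genes, and a fit with per-library loess offsets (span 0.3) for GC content and length, also with camera's estimated correlation, were added after seeing the data.

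The scripts were tested on simulated counts for 19027 genes. At an adjusted p under 0.05, edgeR recovered 1.49% of 67 genes changed 1.5-fold, 28.4% of 67 changed 2-fold and 68.2% of 66 changed 4-fold, with 10.5% of its calls false, and DESeq2 recovered 10.4%, 56.7% and 72.7%, with 33.3% false. The 1 changed list was called and 0 others were. Only the genes counted above and that list were changed, a far smaller share than the 55.3% called in the data. The simulation also held no trend with GC content or length. These rates therefore describe the simulation and not the sensitivity or error rate of the comparison itself. Python 3.11.15 drew the figures.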

Results

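RNA was sequenced from T24 cells, an established human bladder carcinoma line, after vehicle or after lipopolysaccharide (LPS) plus nigericin, with 3 libraries per group. LPS is a bacterial cell wall component sensed by the receptor TLR4, and nigericin is a potassium ionophore that activates the NLRP3 inflammasome, the complex that switches on caspase-1. The series is about caspase-1 in epithelial cells and neutrophil inflammation, and the comparison asks which transcripts differ after this treatment. The labels name no group given LPS alone or nigericin alone. No change described here can therefore be assigned to either agent, or to inflammasome activation, rather than to the combined treatment. The 3 vehicle libraries held 89152224, 81917343 and 82429803 gene counts, and the treated libraries 66180407, 86594539 and 85513548. Of 37871 genes listed, 19170 had enough counts to be tested. Levels are given as CPM (counts scaled to 1e6 per library), mean ± SD over n = 3 libraries per group, and adjusted p-values are Benjamini-Hochberg values from the edgeR quasi-likelihood test over these 19170 genes unless another test is named. The dose and the length of treatment are not given in the sources used here. Nothing in the labels says that the libraries came from separate cultures, so the p-values measure the spread between these libraries, which can be technical. The labels also do not say whether the libraries of both groups were prepared and sequenced together. A difference in preparation between the groups is therefore not separated from the treatment in any value given here.

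After LPS plus nigericin, 10610 of the 19170 tested genes (55.3%) passed the threshold, of which 5540 were higher and 5070 lower than in vehicle. A correction for GC content and length in each library was chosen after seeing the data. It also removes any effect of the treatment that follows either property. With it, 9397 genes passed. Of these, 6697 were among the 10610 with the same direction and 414 with the opposite direction. Changes of at least 2-fold were seen in 3413 of the higher and 2735 of the lower genes, and of at least 4-fold in 1155 and 831. SEMA4A, a membrane semaphorin with roles in immune cells, rose 90.0-fold from 0.349 ± 0.0424 to 31.6 ± 1.31 CPM (log2 fold change 6.49, SE 0.177, edgeR adjusted p = 6.65e-06), and TBR1, a transcription factor of cortical neurons, rose from 0.0759 ± 0.0483 to 7.67 ± 0.770 CPM (log2 fold change 6.61, SE 0.390). HPS6, a component of the complex that forms lysosome-related organelles, fell from 53.2 ± 8.28 to 3.15 ± 0.465 CPM (log2 fold change -4.08, SE 0.191, edgeR adjusted p = 2.09e-05), and CCDC71 fell from 46.6 ± 10.4 to 2.17 ± 0.478 CPM (log2 fold change -4.42, SE 0.250).

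The other genes with the largest rises were DIPK2B, DNALI1, an axonemal dynein light chain, LSMEM1 and RFTN2, with log2 fold changes of 6.16, 6.05, 5.63 and 5.61 and vehicle means of at most 0.179 CPM. The other large falls were those of PARS2, the mitochondrial prolyl-tRNA synthetase, at -4.45, and of BMF, a pro-apoptotic BH3-only protein, at -4.02. BEST1, a chloride channel gene whose exons overlap those of the ferritin gene FTH1, had a log2 fold change of -7.06 (SE 1.46, edgeR adjusted p = 0.00870), and its vehicle libraries differed widely, at 821, 21.1 and 187 CPM. Without vehicle library 1 the BEST1 value was -5.35. The read-through gene TMEM256-PLSCR3, whose exons overlap those of TMEM256 and PLSCR3, had a value of -3.93 (SE 1.33, edgeR adjusted p = 0.0484) that rested largely on vehicle library 2, at 89 CPM against 3.30 and 7.45 in the other vehicle libraries. Without that library it was -1.31. The TMEM256-PLSCR3 call was lost with RLE factors, limma-voom, no count filter or the correction for GC content and length, and without vehicle library 3 or any treated library (edgeR or limma adjusted p = 0.0501 to 0.144). TBR1 was at 7.27 without vehicle library 1, and with the correction for GC content and length LSMEM1 was at 5.04, RFTN2 at 4.58, CCDC71 at -3.69 and HPS6 at -3.19.

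On the GRCh38 assembly, SEMA4A (ENSG00000196189) spans 156147366 to 156177752 on the plus strand of chromosome 1, and its start lies 7277 bases behind the 3' end of LMNA. TBR1 (ENSG00000136535) spans 161416094 to 161425870 on the plus strand of chromosome 2, 4377 bases behind PSMD14, and shares exon sequence with SLC4A10. HPS6 (ENSG00000166189) is a single-exon gene at 102065390 to 102068038 on the plus strand of chromosome 10, and CCDC71 (ENSG00000177352) has 2 exons at 49162535 to 49166321 on the minus strand of chromosome 3. LSMEM1 shares exon sequence with IFRD1 and BMF with BMF-AS1. In all, 27 of the 73 genes named by the rule set in advance share at least 50 bases of exon with another annotated gene, and because the strand setting of the counting is not given, their counts can include reads of the other gene.

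The first principal component of the log2 CPM held 70.1% of the variance and separated the groups, and replicates correlated at 0.965 to 0.978 within groups against 0.880 to 0.923 between them (Pearson, across genes, which are not independent replicates). The 3 treated and 3 vehicle values did not overlap for 12843 tested genes (67.0%), where chance gives 10%. Transcript composition moved with the groups. Among 13976 protein-coding genes, 58.5% of the quintile with the lowest GC content were higher and 5.19% lower after treatment, against 7.08% and 60.9% of the quintile with the highest. Each library's log2 CPM minus the mean of the 6 was correlated with GC content across these genes. The Spearman correlations were 0.508, 0.615 and 0.196 in vehicle libraries 1 to 3 and -0.548, -0.436 and -0.495 in treated libraries 1 to 3. The trend thus also differed among vehicle replicates. By transcript length, 14.6% of the shortest quintile were higher and 43.9% lower, against 55.2% and 10.9% of the longest. Genes of the mitochondrial genome took 6.49% to 7.33% of the counts in vehicle and 12% to 12.4% after treatment, and mitochondrial rRNA took 0.446% to 0.469% and 4.31% to 4.63%.

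**Figure D1:**
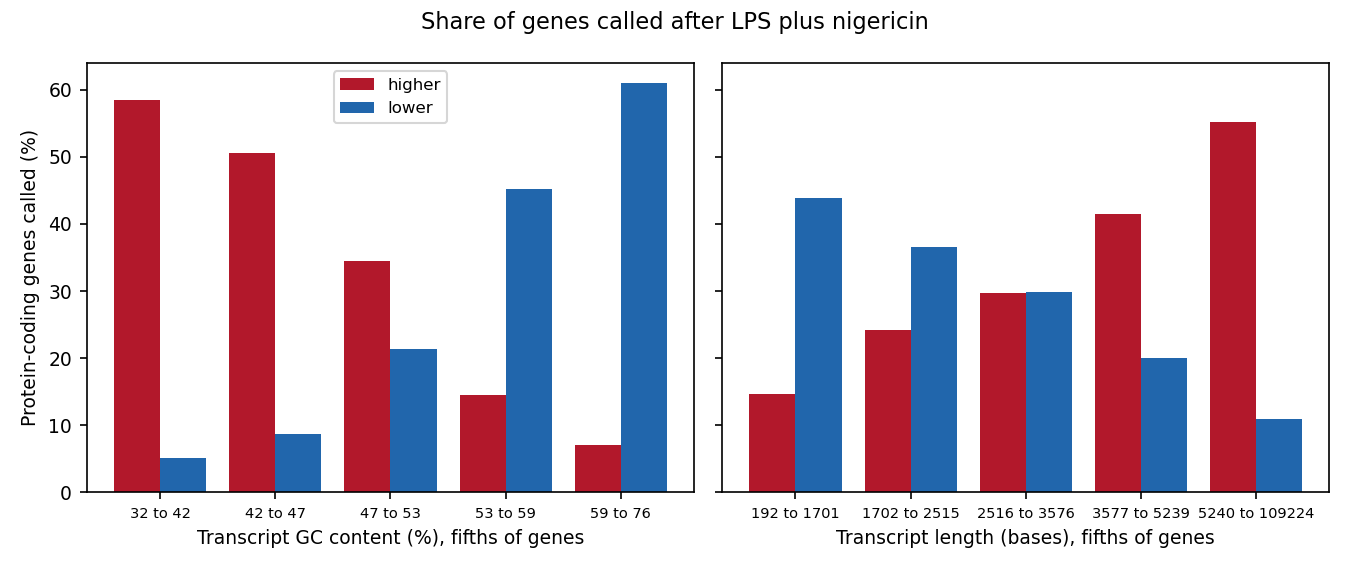
Bars give the percent of protein-coding genes called higher (red) or lower (blue) after LPS plus nigericin in each quintile of genes by transcript GC content in percent (left) or transcript length in bases (right), with an edgeR adjusted p under 0.05 as the threshold. The share called higher runs from 58.5% in the lowest GC quintile to 7.08% in the highest.

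CXCL8, CSF2, CSF3 and IL1A rose, while PYCARD, CASP1, GSDMD, NLRP3 and CASP4 fell. Of 12 inflammasome, receptor and cytokine genes fixed in advance, 9 passed the threshold, 4 higher and 5 lower. Of all tested genes 55.3% passed, so a count of this size is not by itself particular to these 12. CXCL8, which encodes the neutrophil chemokine interleukin-8, rose 11-fold from 67.9 ± 23.6 to 748 ± 58.0 CPM (log2 fold change 3.46, SE 0.263, edgeR adjusted p = 7.57e-05), and CSF2, which encodes GM-CSF, rose 7.40-fold from 4.96 ± 2.96 to 36.8 ± 7.89 CPM (log2 fold change 2.89, SE 0.406, edgeR adjusted p = 8.14e-04). IL1A rose from 7.44 ± 1.62 to 15.6 ± 2.98 CPM (log2 fold change 1.07), and CSF3, which encodes G-CSF, rose from 92.2 ± 7.0 to 119 ± 14.7 CPM (log2 fold change 0.37, SE 0.128, edgeR adjusted p = 0.0399). PYCARD, the ASC adaptor that links NLRP3 to caspase-1, fell from 40.7 ± 13.7 to 11.9 ± 2.01 CPM (log2 fold change -1.78, SE 0.253, edgeR adjusted p = 8.51e-04).

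CASP1 itself fell from 14.6 ± 1.49 to 9.12 ± 0.951 CPM (log2 fold change -0.68, SE 0.154, edgeR adjusted p = 0.00655). GSDMD, which encodes the pore-forming protein of pyroptosis, fell from 156 ± 29.1 to 87.2 ± 10.7 CPM (-0.84 on the log2 scale, edgeR adjusted p = 0.00351). NLRP3, at 4.67 ± 0.386 and 2.91 ± 0.612 CPM, and CASP4, which encodes the sensor of cytosolic LPS, at 121 ± 23.6 and 86.5 ± 3.56 CPM, had log2 fold changes of -0.69 and -0.49 (edgeR adjusted p = 0.0261 and 0.0244). IL1B did not pass the threshold, with 184 ± 21.1 CPM in vehicle and 201 ± 13.8 CPM after treatment (log2 fold change 0.13, SE 0.122, edgeR adjusted p = 0.399). IL18 was at 66.9 ± 1.13 and 57.9 ± 4.93 CPM (edgeR adjusted p = 0.143), and TLR4 at 19.0 ± 4.03 and 18.2 ± 1.5 CPM (edgeR adjusted p = 0.774). These are RNA levels and carry no measure of caspase-1 cleavage or cytokine release.

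With the correction for GC content and length, GSDMD was at 0.11 (edgeR adjusted p = 0.170), PYCARD at -0.60, CASP1 at -1.28 and IL1A at 0.43. CSF3 was at 1.15, and TLR4 and IL18 passed the threshold at -1.25 and -0.58. The correction cannot tell a technical trend from one that the treatment caused, and without it TLR4 and IL18 did not pass. The CSF3 call was lost with RLE factors, library totals, DESeq2 or no count filter (edgeR or DESeq2 adjusted p = 0.05003 to 0.0755) and without vehicle library 1 or 3 or treated library 2 or 3, the CASP4 call without vehicle library 1 or any of the treated libraries, and the NLRP3 call without vehicle library 1 or 3 or treated library 2 or 3. CSF2 was at 3.48 without vehicle library 1. CXCL8 (ENSG00000169429) lies at 73740506 to 73743716 on the plus strand of chromosome 4, PYCARD (ENSG00000103490), which overlaps PYCARD-AS1, at 31201485 to 31203450 on the minus strand of chromosome 16, and CASP1 (ENSG00000137752) at 105025443 to 105035250 on the minus strand of chromosome 11.

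**Figure D2:**
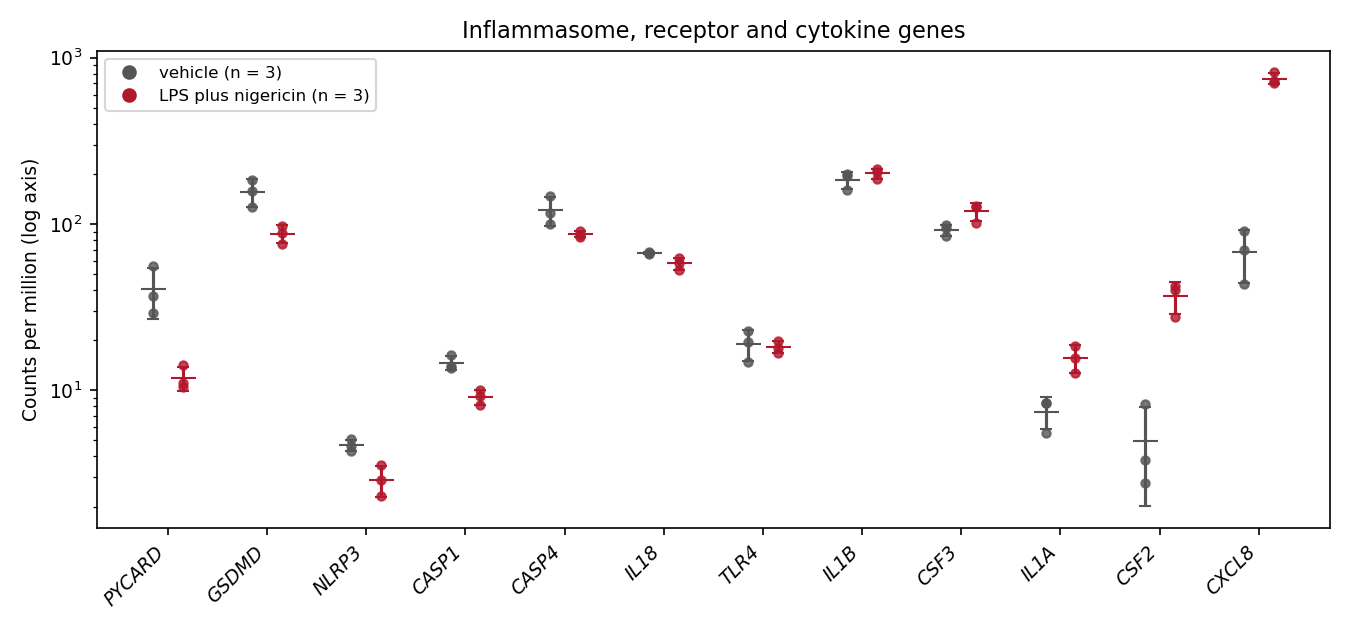
CPM on a log axis for the 12 inflammasome, receptor and cytokine genes, ordered by log2 fold change, with 1 point per library, and the mean and SD of 3 vehicle (grey) and 3 treated (red) libraries. CXCL8 lies at 748 CPM after treatment against 67.9 CPM in vehicle, and the IL1B values of the groups overlap.

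Among 27 gene lists fixed in advance, 7 were higher and 4 lower than the other genes by limma's camera test at its preset correlation. None of these 11 calls held when camera estimated the correlation between genes of a list, where 2 lists had unadjusted p-values under 0.05 (adjusted p = 0.513 or above). By fry, which asks whether a list's genes move on balance in one direction without comparing them with other genes, 20 lists passed. The counts of genes that rose or fell in each list below stand against 55.3% of all 19170 tested genes that passed, 5540 higher and 5070 lower. A count near that share does not set a list apart. The list of neutrophil chemokines and colony-stimulating factors also holds other cytokines and chemokines, IL11 and CCL20 among them. Of its 21 measured genes, 16 rose, 0 fell and 5 did not pass, and adjusted over the list alone 16 rose (median log2 fold change 2.43, camera adjusted p = 1.04e-05; adjusted p = 0.513 with an estimated correlation). CXCL1, a neutrophil chemokine, rose from 113 ± 27.1 to 803 ± 38.3 CPM (log2 fold change 2.83), IL11, an IL-6 family cytokine, from 21.3 ± 1.70 to 126 ± 13.9 CPM (2.56), and CCL20 from 0.119 ± 0.0134 to 3.24 ± 0.392 CPM (4.74). The members that did not pass were CCL5, IL24, IL23A, IL17C and CX3CL1, between -0.27 and 0.76.

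Of 42 interferon-stimulated genes, 28 rose, 4 fell and 10 did not pass, and adjusted over the list alone 30 rose and 4 fell (median 1.12, camera adjusted p = 7.03e-05; adjusted p = 0.513 with an estimated correlation). OAS3, a sensor of double-stranded RNA, rose from 81.3 ± 7.95 to 302 ± 31.8 CPM (log2 fold change 1.89), and HERC6 from 23.1 ± 1.97 to 68.5 ± 3.60 CPM (1.56). The members that fell were OASL (-1.01), IRF9, an interferon-regulated transcription factor (-0.88), IFIT5 (-0.74) and ISG20 (-0.63). The list is GC-poor, with a median of 44.2% against 50.1% in all protein-coding genes, and its median was 0.81 with the correction for GC content and length.

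Of 28 NF-kB target genes, 15 rose, 5 fell and 8 did not pass, with the same counts adjusted over the list alone (median 0.77, camera adjusted p = 0.0259; adjusted p = 0.513 with an estimated correlation). ICAM1, an adhesion molecule bound by leukocytes, rose from 27.7 ± 2.93 to 134 ± 1.19 CPM (log2 fold change 2.28), TNFAIP3, which encodes the NF-kB inhibitor A20, from 12.8 ± 3.22 to 109 ± 11.7 CPM (3.08), and CD83 from 1.84 ± 0.406 to 28.2 ± 5.37 CPM (3.94). IRF1 (-1.92), BCL3 (-1.44), IER3 (-0.77), IL15RA (-0.44) and RELA, the p65 subunit of NF-kB (-0.35), fell. The list call was lost without vehicle library 3 (camera adjusted p = 0.0582).

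Of 22 cytosolic heat shock genes, 15 rose, 3 fell and 4 did not pass, with the same counts adjusted over the list alone (median 0.96, camera adjusted p = 0.00933; adjusted p = 0.513 with an estimated correlation). HSPA6, a stress-inducible HSP70 close in sequence to HSPA7, rose from 1.69 ± 0.140 to 69.0 ± 11.1 CPM (log2 fold change 5.35, SE 0.184), or by 5.97 with the correction for GC content and length, and the co-chaperone genes DNAJA1 and DNAJB1 rose by 1.91 and 1.63 on the log2 scale. The small heat shock gene HSPB1 (-0.79), the chaperonin gene HSPE1 (-0.58) and HSPA1L (-1.81) fell. Of 37 immediate early and AP-1 genes, 17 rose, 4 fell and 16 did not pass, and adjusted over the list alone 18 rose and 4 fell (median 0.46, camera adjusted p = 0.0417; adjusted p = 0.589 with an estimated correlation). The EGF receptor ligand genes HBEGF, from 30.6 ± 1.49 to 186 ± 8.22 CPM, and AREG, from 6.43 ± 0.829 to 38.6 ± 0.705 CPM, rose by 2.60 and 2.59 on the log2 scale, and MAFF by 2.26, or 2.94 with the correction. The list's median was 0.83 with the correction. MYC (-2.26), DUSP6 (-2.0), DUSP4 (-1.47) and FOSL1 (-0.60) fell. This list's call was lost under the stricter count filter and without vehicle library 2 or treated library 2 (camera adjusted p = 0.0732, 0.0999 and 0.0630).

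Of 40 lysosome and autophagy genes, 20 rose, 2 fell and 18 did not pass, with the same counts adjusted over the list alone (median 0.34, camera adjusted p = 0.0123; adjusted p = 0.513 with an estimated correlation). ATP6V1C1, a subunit of the proton pump that acidifies lysosomes, rose by 2.54 on the log2 scale and by 1.55 with the correction for GC content and length, GABARAPL1, an autophagosome protein, by 1.89, and FLCN, which acts in nutrient sensing at the lysosome, by 1.85. The list's median was 0.64 with the correction. TFEB, the transcription factor of lysosomal genes (-1.77), and WIPI1 (-0.49) fell. The list call was lost without vehicle library 3 (camera adjusted p = 0.0630). Of 32 mesenchymal and matrix genes, 17 rose, 2 fell and 13 did not pass, with the same counts adjusted over the list alone (median 0.46, camera adjusted p = 0.0172; adjusted p = 0.589 with an estimated correlation). SNAI1, a repressor of epithelial genes, rose from 2.5 ± 0.539 to 27.7 ± 1.70 CPM (log2 fold change 3.47), CDH2, which encodes N-cadherin, from 34.1 ± 6.22 to 117 ± 14.7 CPM (1.78), and FN1, fibronectin, by 1.29 on the log2 scale. With the correction SNAI1 was at 4.17 and CDH2 at 1.15. SNAI2 (-1.37) and ITGA5 (-0.60) fell. The list call was lost under the stricter count filter (camera adjusted p = 0.0732).

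Of 46 nuclear genes of oxidative phosphorylation, 28 fell, 1 rose and 17 did not pass, and adjusted over the list alone 29 fell and 1 rose (median -0.51, camera adjusted p = 8.87e-04; adjusted p = 0.589 with an estimated correlation). The complex I gene NDUFB9, which overlaps TATDN1, fell from 165 ± 36.3 to 31.8 ± 2.91 CPM (log2 fold change -2.37), NDUFV2 from 87.8 ± 8.18 to 25.4 ± 2.45 CPM (-1.79), and UQCRFS1, the Rieske protein of complex III, from 60.1 ± 6.16 to 16.1 ± 2.07 CPM (-1.90). UQCRC2 rose by 0.32 on the log2 scale. These transcripts are short, with a median of 1048 bases against 2990 in all protein-coding genes, and their median was -0.35 with the correction for GC content and length.

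Of 42 genes of DNA replication and S phase, 21 fell, 3 rose and 18 did not pass, with the same counts adjusted over the list alone (median -0.44, camera adjusted p = 0.0263; adjusted p = 0.589 with an estimated correlation). MCM5, a subunit of the replicative helicase, fell from 334 ± 70.3 to 110 ± 6.99 CPM (log2 fold change -1.60), CHAF1A, a histone chaperone subunit, from 107 ± 18.4 to 48.0 ± 0.903 CPM (-1.15), and POLD1, the catalytic subunit of DNA polymerase delta, from 151 ± 23.5 to 78.8 ± 3.16 CPM (-0.94). POLD1 was at -0.18 with the correction for GC content and length. The members that rose included POLA1 (1.06) and RRM1 (0.71), and the list call was lost without vehicle library 3 or treated library 2 (camera adjusted p = 0.0582 and 0.0630).

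Of 18 measured urothelial and epithelial markers, 11 fell, 1 rose and 6 did not pass, and adjusted over the list alone 12 fell and 1 rose (median -1.0, camera adjusted p = 0.00933; adjusted p = 0.589 with an estimated correlation). KRT18, a simple epithelial keratin, fell from 1536 ± 273 to 471 ± 66.9 CPM (log2 fold change -1.71), KRT15 from 10.8 ± 1.61 to 3.42 ± 0.768 CPM (-1.66), and PPARG, a regulator of urothelial differentiation, from 83.5 ± 3.88 to 40.6 ± 2.89 CPM (-1.04). ST14, which encodes matriptase, rose by 3.31. This list is GC-rich, with a median of 59.8%, and with the correction for GC content and length its median was -0.40 and its call was lost (camera adjusted p = 0.189), with KRT18 at -0.86.

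Of 77 cytosolic ribosomal protein genes, 20 fell, 5 rose and 52 did not pass, and adjusted over the list alone 11 fell and 3 rose (median -0.31, camera adjusted p = 0.00933; adjusted p = 0.711 with an estimated correlation). RPL35 fell from 741 ± 210 to 335 ± 44.6 CPM (log2 fold change -1.14), RPL36 by 0.80 and RPS14 by 0.72 on the log2 scale. RPS28 (1.29), RPL7 (0.44), RPL22 (0.40), RPS12 (0.37) and RPS3A (0.36) rose. These transcripts have a median of 891 bases, and with the correction for GC content and length the list's median was -0.08 and its call was lost (camera adjusted p = 0.682), with RPL36 at 0.33 and RPL35 at -0.34. By fry, which does not compare a list with other genes, the list did not pass (limma adjusted p = 0.204). Many ribosomal protein genes have near-identical pseudogenes, so their counts are uncertain.

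**Figure D3:**
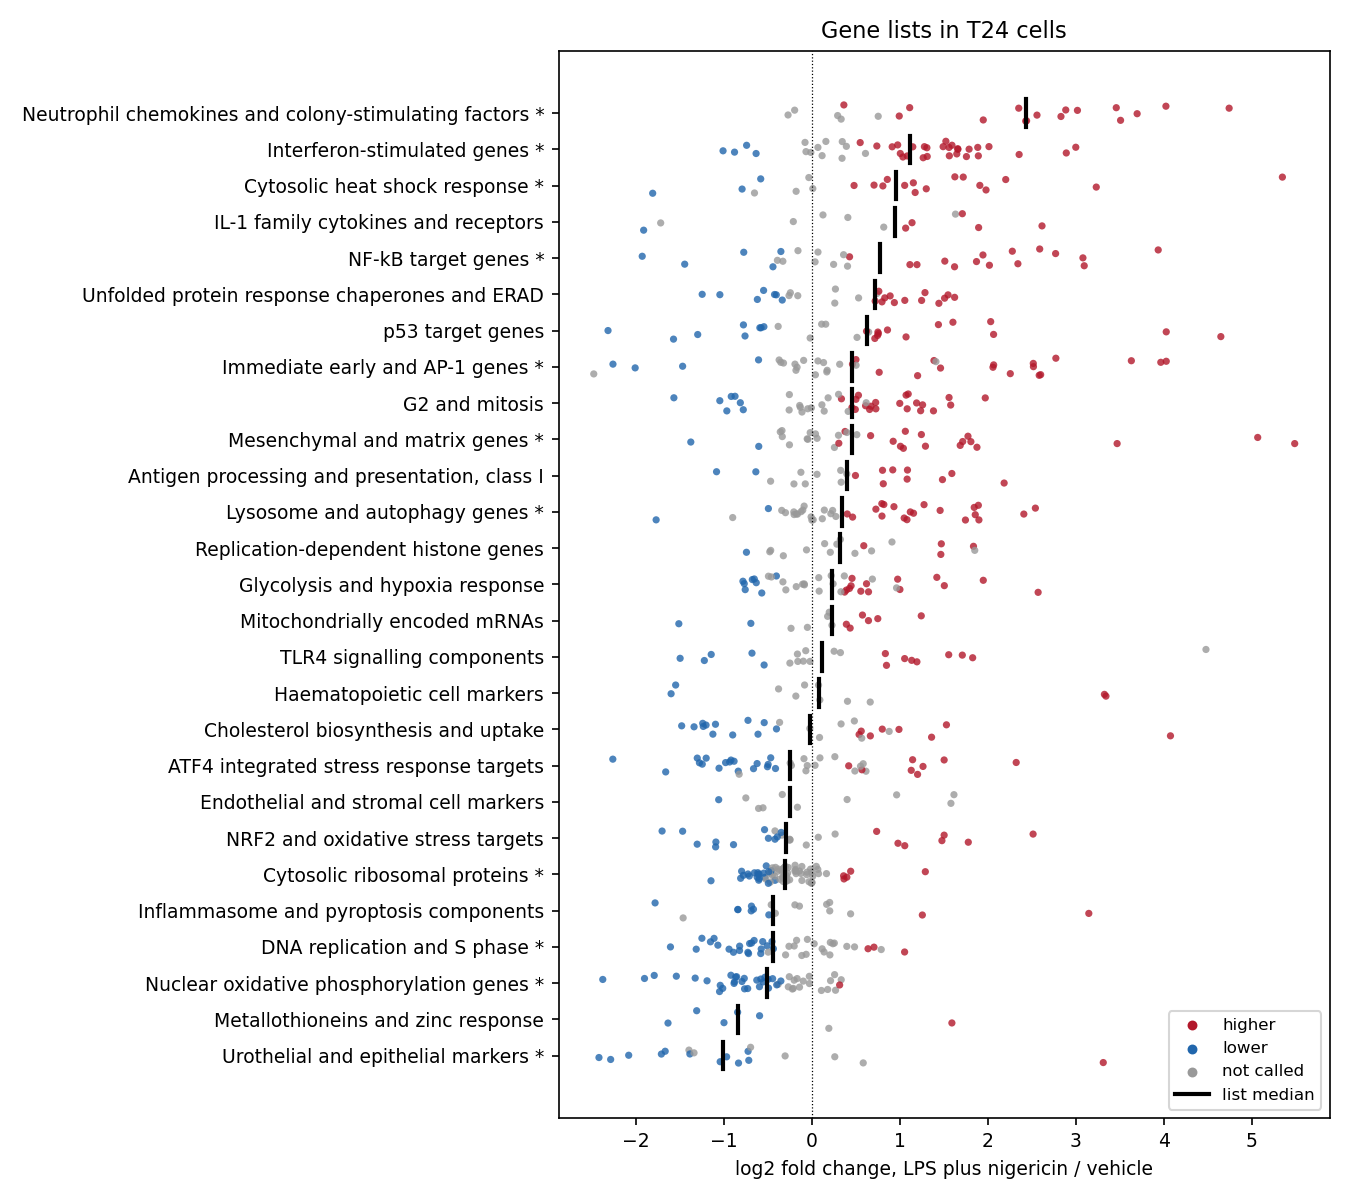
Each point is the log2 fold change of 1 measured gene after LPS plus nigericin, grouped by the 27 gene lists and coloured by whether the gene was called higher (red), lower (blue) or not called (grey), with a black bar at the list median and an asterisk where camera's adjusted p was under 0.05. Medians run from 2.43 for neutrophil chemokines and colony-stimulating factors to -1.0 for urothelial and epithelial markers.

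The other 16 lists did not pass camera's threshold, and in most of them genes moved in both directions. Of 18 inflammasome and pyroptosis components, 2 rose, 7 fell and 9 did not pass (camera adjusted p = 0.240), with the same counts adjusted over the list alone. The median of this list was -0.44, or -0.64 with the correction for GC content and length. NLRP1, an inflammasome sensor of epithelial cells, fell from 144 ± 4.85 to 80.3 ± 5.41 CPM (log2 fold change -0.84), while AIM2, a sensor of cytosolic DNA, rose by 3.15, and NEK7, a partner of NLRP3, rose by 1.26. AIM2 was barely detected, at 0.0512 ± 0.0456 CPM in vehicle and 0.477 ± 0.310 CPM after treatment (edgeR adjusted p = 0.0251). Of 12 IL-1 family cytokines and receptors, 5 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.243, median 0.94, or 0.41 with the correction for GC content and length). IL18R1 (2.62), IL1RL1 (1.90), IL1RAP (1.71), IL33 (1.14) and IL1A rose, and IL37, an anti-inflammatory member, fell by 1.91 on the log2 scale. IL18R1 and IL1RL1 were barely detected, with means of 0.0804 and 0.149 CPM in vehicle and 0.513 and 0.562 CPM after treatment (edgeR adjusted p = 0.0439 and 0.0446). Of 22 components of TLR4 signalling, 8 rose, 5 fell and 9 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 0.482), and TAB2, an adaptor of the kinase TAK1, was at 1.83, or 0.87 with the correction for GC content and length. LY96, a member that did not pass, was barely detected, at 0.142 ± 0.0769 CPM in vehicle and 0.139 ± 0.124 CPM after treatment. CD14, another, was at 3.43 and 3.06 CPM.

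Of 19 class I antigen presentation genes, 9 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.133), and HLA-B was at 1.49. With the correction for GC content and length HLA-B was at 2.55 and this list passed camera's threshold (adjusted p = 2.61e-04), but not with an estimated correlation (adjusted p = 0.124). Of 27 chaperone and degradation genes of the unfolded protein response, 13 rose and 7 fell, and adjusted over the list alone 15 rose and 7 fell (camera adjusted p = 0.151, median 0.72, or 0.19 with the correction). HSPA5, the chaperone BiP, rose from 271 ± 33.2 to 836 ± 48.9 CPM. Of 39 ATF4 targets of the integrated stress response, 8 rose and 18 fell, and adjusted over the list alone 9 rose and 18 fell (camera adjusted p = 0.191). The median of this list was -0.24, or -0.06 with the correction. PPP1R15A, which encodes the eIF2 phosphatase subunit GADD34, rose from 196 ± 20.7 to 983 ± 93.5 CPM, and was at 2.32 on the log2 scale, or 2.97 with the correction. Of 27 p53 targets, 13 rose and 8 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.277, median 0.62, or 0.23 with the correction), and BTG2, an antiproliferative gene, was at 4.03.

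Of 41 G2 and mitosis genes, 21 rose and 7 fell, and adjusted over the list alone 21 rose and 8 fell (camera adjusted p = 0.151). PLK1, a mitotic kinase, fell from 469 ± 65.5 to 158 ± 12.2 CPM. The list has a median GC content of 42.9%, and its median log2 fold change was 0.46, or 0.03 with the correction for GC content and length. Of 17 replication-dependent histone genes, 4 rose and 1 fell, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.277), with H4C8 at 1.84. Of 38 genes of glycolysis and hypoxia, 14 rose and 8 fell, and adjusted over the list alone 15 rose and 9 fell (camera adjusted p = 0.360), and ADM, adrenomedullin, was at 2.57, or 3.22 with the correction. Of 26 NRF2 targets and oxidative stress genes, 7 rose and 11 fell, and adjusted over the list alone 7 rose and 12 fell (camera adjusted p = 0.277). The median of this list was -0.29, or -0.01 with the correction. KEAP1, which holds NRF2 in check, was at -1.47, or -0.81 with the correction.

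Of 27 genes of cholesterol synthesis and uptake, 8 rose and 12 fell, and adjusted over the list alone 10 rose and 13 fell (camera adjusted p = 0.499). MVK, mevalonate kinase, was at -1.24, or -0.59 with the correction. The median of this list was -0.02 and its mean 0.02, so they differed in sign. Of 7 metallothionein and zinc response genes, 5 fell and 1 rose, with the same counts adjusted over the list alone (camera adjusted p = 0.188). The metallothionein MT1E fell from 291 ± 47.7 to 94.0 ± 13.3 CPM. The transcripts of this list are short, with a median of 690 bases, and its median was -0.84, or -0.12 with the correction for GC content and length. Of 13 mRNAs encoded by the mitochondrial genome, 6 rose and 2 fell, with the same counts adjusted over the list alone (camera adjusted p = 0.310), and MT-ND4L rose by 1.25 on the log2 scale. Markers of other cell types were tested as well. Of 11 measured haematopoietic markers, 2 rose and 2 fell (camera adjusted p = 0.916, with camera's direction down against a median of 0.08 and a mean of 0.38), and of 10 endothelial and stromal markers, 1 fell and 9 did not pass (camera adjusted p = 0.673, median -0.25, mean 0.11). Counts adjusted over the list alone were the same for both. LYZ (3.34) and CD79A (3.33) rose, and CORO1A (-1.60), CD68 (-1.54) and the endothelial receptor gene ENG (-1.06) fell, with CORO1A at -0.69 and ENG at -0.29 with the correction for GC content and length.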

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

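The GC and length offsets, alone or with an estimated correlation, and the fit without mitochondrial and 5.8S rRNA genes were chosen after seeing the data. Across the RLE factors, library totals, DESeq2, limma-voom, both count filters, the replicate block and the fit without mitochondrial genes, 9452 to 11345 genes were called, and 0 genes called both there and in the reported test had the opposite direction. With library totals 46.2% of calls were higher, against 52.2%. Leaving out 1 library gave 8341 to 11347 genes (4341 to 6061 higher, 4000 to 5286 lower), 8 to 11 lists (5 to 7 higher, 3 to 4 lower) and 6 to 9 of the 12 fixed genes.

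Testing against a 2-fold change called 2684 genes, 1512 higher and 1172 lower, a stricter question by construction. Camera with an estimated correlation called 0 lists (0 higher, 0 lower; 2 at an unadjusted p under 0.05). Fry called 20 lists, 12 higher and 8 lower, and 27 for change in either direction, since it does not compare lists with other genes. With GC and length offsets 9397 genes passed. Of 7111 called in both fits, 414 had the opposite direction, and 10 lists passed instead of 11 (8 higher instead of 7, 2 lower instead of 4). With these offsets and an estimated correlation camera called 0 lists (0 higher, 0 lower, and 7 at an unadjusted p under 0.05). RPL36 reversed to 0.33 (edgeR adjusted p = 0.0156) and GSDMD to 0.11 (0.170). Where no construction is named, the cause was not tested.

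Replicate numbers did not pair the libraries: correlations of same-numbered deviations were -0.023, 0.096 and -0.024, and replicate 2 alone matched its own number best. With the replicate block 10408 genes, 10 lists and 8 of the 12 genes passed. The calls lost with it among named results were BEST1, TMEM256-PLSCR3, CSF3 and the immediate early list (adjusted p = 0.113, 0.227, 0.0613 and 0.0586). Rounding down was not run, since the counts are whole.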

Other observations

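The tests of ribosomal RNA were chosen after the result was seen, as were the genes named for it and the GC and length offsets. Ribosomal RNA rose far more than mRNA from the mitochondrial genome, and counts at mitochondrial tRNA genes fell. The mitochondrial 16S rRNA gene MT-RNR2 rose 10.3-fold, from 3830 ± 377 to 39506 ± 1097 CPM (n = 3 per group), and the 12S rRNA gene MT-RNR1 8.56-fold, from 653 ± 133 to 5590 ± 289 CPM. Of 22 mitochondrial tRNA genes tested, 21 fell, 0 rose and 1, MT-TP, did not pass (edgeR), with a median log2 fold change of -2.49. Vehicle means of these tRNA genes ran from 0.879 to 173 CPM. The strand setting of the counting is not given, so their counts can include reads of other mitochondrial transcripts. The light-strand mRNA MT-ND6 (-1.51) and MT-ND3 (-0.69) fell, and the median over the 13 mRNAs was 0.23. The 4 genes of 5.8S rRNA, which is made in the nucleolus, rose by 4.13 to 4.54 on the log2 scale, MIR3648-1 and MIR3648-2 by 4.68 and 4.37, and the small nucleolar RNA SNORD3A by 3.92. Their vehicle levels were low, with means of 1.66 to 2.49 CPM for the 5.8S genes. MIR3648-1, MIR3648-2 and SNORD3A had vehicle means of 0.291, 0.195 and 0.909 CPM. The nuclear long noncoding RNAs NEAT1 and MALAT1 rose by 2.65 and 1.43.

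An even carryover of ribosomal RNA into the treated libraries stays open. The log2 fold changes of the rRNAs spanned 1.45, with a largest replicate SD of 0.292, which met the bound written for arguing against an even carryover. That bound took no account of vehicle levels, so it was set aside and does not decide. Carried-over RNA adds counts and the vehicle levels of these genes ran from 1.66 to 3830 CPM, so unequal folds are possible with an even carryover. A larger share of mitochondrial RNA as a whole is argued against, since the highest of the 13 mRNAs, MT-ND4L, lay 1.85 below the lower of the 12S and 16S values. A difference between the groups in how rRNA was removed or captured, and the treatment itself, were not tested and stay open too.

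Among the named genes with the largest rises, TBR1 lies 4377 bases behind PSMD14 and SEMA4A 7277 bases behind LMNA, both on the same strand as the neighbour. RFTN2 and DIPK2B lie 14525 and 35772 bases behind an expressed gene on the opposite strand. DNALI1 and LSMEM1 overlap an expressed gene, but so do BEST1 and TMEM256-PLSCR3 among the largest falls. The share of all tested genes placed in these ways was not computed. SEMA4A is expressed too highly to be in the set compared next. Across genes with a mean under 5 CPM and no overlap with an expressed gene, the 909 within 10 kb behind the 3' end of an expressed gene had a median log2 fold change of 0.21, against -0.57 for the 701 within 10 kb in front of a 5' end. The difference was 0.781 (95% bootstrap interval 0.648 to 0.934, permutation p = 1e-05, the smallest that 100000 permutations can give), and 0.818 (0.681 to 0.969) with the GC and length offsets, which argues against GC content and length as its whole cause. All intervals and permutation p-values in this paragraph resample genes, which are not independent replicates, and hold no spread between libraries. Transcripts that run on past the neighbour's end may contribute, since the difference passed the bound set in advance (over 0.5), but a requirement added after the values were seen, that the 3' side lie above genes more than 50 kb away, was met with the offsets (0.440, 0.320 to 0.550) and not without them (0.084, -0.043 to 0.209), where low values in front of 5' ends (-0.697 against distant genes) make up most of the gap. Whether run-on transcription contributes beside the lower values in front of 5' ends stays open: genes on the neighbour's strand lay 0.222 above those on the opposite strand (-0.030 to 0.509, permutation p = 0.0376), an interval that includes 0, and genes 10 to 50 kb behind a 3' end had a median of 0.31 (188 of 648 called higher), no lower than the 0.21 (225 of 909) within 10 kb.

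Protein-coding genes with 1 or 2 exons were lower: their median log2 fold change lay -0.744 (95% bootstrap interval -0.868 to -0.640, 1068 against 12908 genes) from that of other protein-coding genes. Of the 6 named genes with the largest falls, HPS6, PARS2 and CCDC71 have 1, 2 and 2 exons, and BMF, BEST1 and TMEM256-PLSCR3 have 5, 9 and 11. With the GC and length offsets the difference was -0.516 (-0.603 to -0.412), more than 50% of its size without them, so GC content and length do not account for all of it. These intervals also resample genes and hold no spread between libraries. No biological explanation was tested.

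For 3 libraries against 3, the 10 splits of the libraries cannot give a share under 0.05, and in each of these 3 results 1 split of the 10, the real one, was as large. The real split gave 10610 genes, and the highest of the others 0 by edgeR (43 to 187 genes at an unadjusted p under 0.05), with 11 lists against 8 and 9 of the fixed genes against 0. Each of the other splits puts treated and vehicle libraries together on both sides, so the group difference adds to the spread within a side. Few gene calls follow from this by construction, so these counts are no measure of chance.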
